A study of Mus musculus with 6 samples.

How the data were processed

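Bulk RNA sequencing was measured in Treg cells of C57BL/6 mice, with RNA extracted in Trizol, in 6 groups of 1 library each: wild type (MondoA+/+ with Foxp3-Cre) and knockout (floxed MondoA with Foxp3-Cre) in resting nTreg cells sorted as CD4+CD25hiYFP+, in stimulated nTreg cells, and in iTreg cells polarized from naive CD4 T cells. Groups were taken from the labels. The values analysed were the deposited expected counts per gene, which per the file headers are estimated numbers of reads and were not normalised. The deposited FPKM values, scaled to transcript length and library size, were used only for alternatives. The deposited transcript length, which is averaged over the transcripts of a gene and differs between libraries for genes with several transcripts, was used for the length trend. The submitters' processing notes name Bowtie2, HISAT and the mm9 build, with no role, order or version. The quantifier, its annotation and the strandedness of the libraries were not given in the sources used here.

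Expected counts were rounded to whole numbers, and 76.0% of the listed values were whole within 0.005 beforehand. Each library lists 15039 to 15624 genes with an FPKM of at least 0.01, and a gene missing from a library was taken as 0. The listing minimum lies under the floor of 3 counts per library that was used for every "at least" fold. Gene identifiers were joined to symbols with a reference table on the GRCm38 assembly, which served only for symbols and for the order of neighbouring genes. Of 17759 identifiers 17711 were matched, and the 48 others, with 0.0561 to 0.0773% of the counts of a library, were kept in the library sizes and tests under their number. Total expected counts per library were 9774183 and 9953513 (wild-type and knockout resting), 10044772 and 10185664 (stimulated), and 9760285 and 10126865 (iTreg). The 10 most abundant genes took 4.33 to 5.51% of the counts and ribosomal protein genes 6.48 to 10.2%. At this depth 50 counts correspond to about 5 CPM.

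Counts were normalised with TMM factors in edgeR 4.0.16 (R 4.3.3), which lay between 0.961 and 1.06 when computed on all genes. For the edgeR model the factors were computed again on the genes left by its filter. The genotype effect shared by the 3 states and the effects of stimulation and of iTreg polarization were tested in 1 additive model of state and genotype, with the edgeR quasi-likelihood test, Benjamini-Hochberg adjustment and a threshold of 0.05. The filter for low counts (filterByExpr, at least 10 counts and 15 in total) left 12848 genes, and 2 residual degrees of freedom remained. The common dispersion of these genes, estimated without TMM factors, was 0.0303. An effect specific to a state counts as error in this model. Standard errors of log2 folds were derived from the F statistic. Gene lists were tested with limma 3.58.1 (camera on log2 CPM, preset correlation 0.01, and with an estimated correlation beside it), adjusted over 29 lists, and members were also adjusted over the list alone with the p-values of the edgeR model. With an estimated correlation the test uses the 2 residual degrees of freedom, so a list that fails it is not shown to be unchanged.

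Within a state, where each genotype had 1 library, no p-value was computed. Log2 folds used CPM with a prior count of 2, and genes were counted at a 2-fold difference and at least 50 counts in the higher library. Ratios have exact conditional (Clopper-Pearson) 95% intervals and levels have Poisson intervals. The median log2 fold of each list was placed among 10000 random lists of the same size, matched on mean expression in 10 bins, as a description. Differences in the stimulation response and correlations of folds between states were described without a test. Calculations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.

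The comparisons, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule named Mlxip, Txnip, Arrdc4, Foxp3 and Slc2a1. It added the 8 largest increases and 8 largest decreases of each genotype pair among genes with at least 50 counts, and those of each model contrast among genes past the threshold with a mean log2 CPM over 3. Where fewer than 8 passed, genes that moved the same way in all 3 pairs followed. Up to 4 members with the largest folds could be named for each list, and some genes that the rule would name are not reported here. Predicted or unnamed models, antigen receptor segments and the 5 genes of the sex-linked list were left out of the ranked parts. There were 30 lists with 418 members besides the ribosomal protein genes, which were chosen by symbol. They covered MondoA targets, the MLX network, the Treg, Th1, Th2, Th17 and follicular helper programmes, naive genes, T cell receptor and interferon responses, homing, cytotoxicity, metabolism, hypoxia, proliferation, TGF-beta response, stress, sex, and markers of B, myeloid, CD8 or NK, erythroid and stromal cells. Gzmd and Gzme had no entry in the tables, and no gene encoded by the mitochondrial genome was listed, so that list was not analysed here.

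The model was tested on simulated data with 200 changed genes. For the genotype effect it recovered 86% of 2-fold and 100% of 4-fold changes with 9 false calls. For stimulation these were 51% and 98% with 3 false calls. False calls were counted among the unchanged of the 12848 genes. Simulated counts followed the trend of dispersion with expression, without a spread of single genes around it, and a genotype change was equal in all 3 states. Real genes that vary more, or differ between states, may be recovered less often. In 1 simulated pair, that of iTreg cells, 124 of 9932 unchanged genes lay beyond 2-fold.

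Alternatives were DESeq2 median-of-ratios size factors, no filter for low counts, DESeq2 1.42.0 in place of edgeR, limma on log2(FPKM + 1), leaving out each library or each pair, no covariate, a prior count of 0.5, count minimums of 20 and 200, and FPKM values of at least 1 for the pairs. Chosen after seeing the data were the removal of the length trend (lowess with span 0.3 on log2 length), log2(FPKM + 0.1), and other settings for the difference in response. For the model and its list tests the trend was fitted on genes with a mean log2 CPM over 3. Within a state it was fitted on genes with at least 50 counts in the higher library of the pair. No paired analysis was possible because each group held a single replicate and nothing links the animals of different states.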

Results

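RNA sequencing compared Foxp3-positive regulatory T (Treg) cells of 8-week-old mice whose MondoA gene, Mlxip, was floxed and deleted by Foxp3-Cre (knockout) with cells of mice carrying Foxp3-Cre and intact MondoA (wild type). Each genotype was measured in 3 cell states: resting nTreg cells sorted from spleen and lymph nodes, nTreg cells stimulated for 48 h with antibodies to CD3 and CD28 and with IL-2, and iTreg cells polarized from naive CD4 T cells for 4 days. There was 1 library in each of the 6 groups, so no value within a state has a replicate check. Total expected counts lay between 9760285 and 10185664 per library, and the interval beside each ratio of 2 libraries is a 95% interval that covers counting error only. Nothing in the labels says that the samples came from separate animals or cultures. The p-values measure only the spread that the model of state and genotype leaves between these samples. That spread mixes genotype effects specific to a state with differences between samples, which may be technical.

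The first question was whether the targeted gene and its known targets differed between the genotypes. Mlxip, which encodes the glucose-responsive transcription factor MondoA, was lower in every knockout library, at 108 against 142 normalised CPM (counts scaled to a library total of 1e6) in resting cells (log2 fold -0.40, 95% interval -0.52 to -0.29), 87.1 against 152 in stimulated cells (-0.80, -0.92 to -0.68) and 70.7 against 167 in iTreg cells (-1.24, -1.37 to -1.11). With a trend with gene length removed, described with the iTreg comparison, these values were -0.30, -0.79 and -0.72. The labels do not say which exons were floxed, so counts of this gene may include reads from outside the deleted part. Txnip, an arrestin-like inhibitor of glucose uptake and a direct MondoA target, was lower by log2 folds of -1.89 (-1.94 to -1.84), -2.52 (-2.74 to -2.34) and -2.06 (-2.18 to -1.94) in the same order. Arrdc4, its paralog and also a MondoA target, was lower by -2.53 (-3.27 to -2.03), -3.89 (-5.99 to -3.07) and -3.85 (-4.60 to -3.37). Foxp3, the lineage factor of Treg cells, lay at 725 CPM in wild-type and 744 CPM in knockout resting cells (0.04, -0.01 to 0.08), at 507 and 527 after stimulation (0.06, 0.00 to 0.11) and at 492 and 482 in iTreg cells (-0.03, -0.09 to 0.03). The sign of the iTreg difference in Foxp3 turned to 0.06 once the length trend was removed. Slc2a1, the glucose transporter GLUT1, differed by 0.02 (-0.15 to 0.19), 0.20 (0.08 to 0.31) and 0.28 (0.14 to 0.42), and the iTreg value was 0.17 with the length trend removed.

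**Figure D1:**
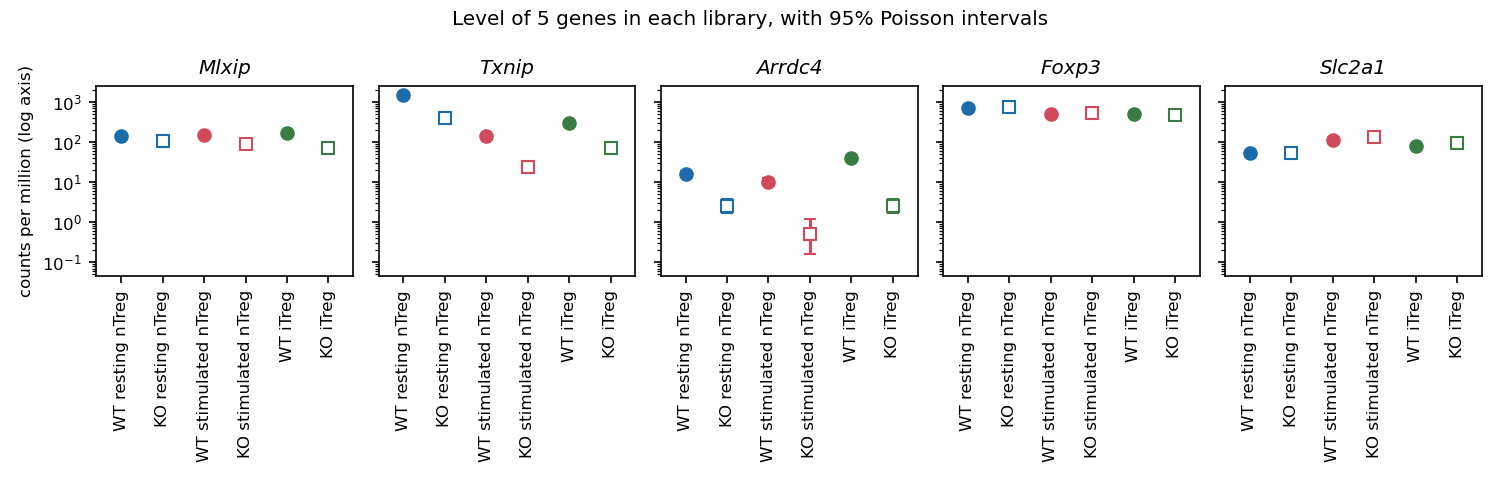
Normalised CPM (log axis) of Mlxip, Txnip, Arrdc4, Foxp3 and Slc2a1 in each of the 6 libraries, with filled circles for wild type, open squares for knockout and bars for 95% Poisson intervals. Txnip stood at 1499 and 405 CPM in the wild-type and knockout resting libraries, while Foxp3 lay between 482 and 744 CPM in all 6.

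The genotype effect shared by the 3 states was tested with all 6 libraries and the cell state as a covariate. Of 12848 genes, 22 passed, 14 higher and 8 lower in knockout cells, and 1019 had an unadjusted p under 0.05. Txnip fell by a log2 fold of -2.15 (standard error 0.185, adjusted p = 0.00171) and Arrdc4 by -3.50 (0.329, adjusted p = 0.00282), so both members of the list of MondoA targets passed, over all genes and adjusted over the list alone. Mlxip itself did not pass (-0.82, standard error 0.182, adjusted p = 0.240), nor did Foxp3 (0.02, adjusted p = 0.972) or Slc2a1 (0.17, adjusted p = 0.729).

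Among the shared decreases, Oasl2, an antiviral oligoadenylate synthetase-like gene that lies within 250 gene positions of Mlxip, fell by -3.83 (0.278, adjusted p = 0.000505). Trim12a and Trim30d, members of the TRIM family of innate immune proteins, fell by -1.74 (0.182, adjusted p = 0.00545) and -1.52 (0.186, adjusted p = 0.0147). Ctse, the aspartic protease cathepsin E, fell by -2.92 (0.293, adjusted p = 0.00439), and Ccl22, a chemokine that attracts CCR4-bearing T cells, by -1.70 (0.258, adjusted p = 0.0482). Ifi204, an interferon-inducible DNA sensor, was lower in all 3 pairs but did not pass (-2.80, 0.726, adjusted p = 0.381).

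Among the shared increases, Gdpd3, a lysophospholipase D, rose by 6.65 (0.317, adjusted p = 2.6e-05). Zan, which encodes the sperm protein zonadhesin and also lies within 250 gene positions of Mlxip, rose by 4.40 (0.482, adjusted p = 0.00737). Lhx6, a LIM-homeobox gene, rose by 2.16 (0.322, adjusted p = 0.0467), Trim16 by 2.14 (0.322, adjusted p = 0.0476), and Spp1, the cytokine osteopontin, by 1.27 (0.18, adjusted p = 0.0360). Atp6v0c-ps2 had 0 counts in the 3 wild-type libraries and a mean of 54.5 CPM in the knockout libraries, at least 181-fold higher against a floor of 3 counts per library (adjusted p = 6.5e-05). Hmga1b rose by 7.17 (0.919, adjusted p = 0.0182) and Tdg-ps2 by 6.28 (0.937, adjusted p = 0.0467). These 3 are near-identical copies of Atp6v0c, Hmga1 and Tdg, and reads may be shared between copy and parent, so their own level is uncertain. In stimulated cells Hmga1b stood at 1.01 CPM in wild type and 299 in knockout while Hmga1 stood at 310 and 95.2. In resting cells Tdg-ps2 had 5 counts in wild type and 0 in knockout, Lhx6 3 and 9 and Spp1 3 and 6, in stimulated cells Lhx6 had 3 and 11, and in iTreg cells Zan had 0 and 3, all too few to give a direction. In the other pairs each named gene that passed lay on the side of its shared effect, Tdg-ps2 at 7.11 and 6.15 in stimulated and iTreg cells.

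Of the other 7 of the 22 genes, Msi1, AA465934 and Acacb were named by the rule only through the genotype pairs. Kcnab3, Gm5779, a gene without a symbol and Gm15441 fell outside the rule and were picked out after their values were seen. Msi1, an RNA-binding protein, rose by 5.04 (0.684, adjusted p = 0.0275) and Acacb, the mitochondrial acetyl-CoA carboxylase, by 2.58 (0.306, adjusted p = 0.0120), and both lie within 250 gene positions of Mlxip. Kcnab3, a potassium channel subunit, rose by 2.10 (0.307, adjusted p = 0.0440), as did AA465934 by 2.63 (adjusted p = 0.0175), the predicted gene Gm5779 by 9.24 (0.45, adjusted p = 2.64e-05) and the gene without a symbol by 4.86 (adjusted p = 0.0117). Gm5779 had 0, 2 and 0 counts in wild-type and 309, 404 and 741 in knockout resting, stimulated and iTreg cells, so its fold rests on 2 wild-type counts. Gm15441 fell by -2.07 (0.181, adjusted p = 0.00171), but it is annotated antisense to Txnip and the strandedness of the libraries is unknown, so its reads may come from Txnip.

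The count of 22 depended on single pairs of libraries. With the cell state in the model, leaving out either library of a state takes that whole pair out of the genotype contrast. Such fits also have fewer residual degrees of freedom than the full model, so more calls or smaller p-values in them are not stronger evidence. It was 235 without the wild-type and 233 without the knockout resting library, 302 and 305 without the wild-type and knockout stimulated libraries, and 35 and 34 without the wild-type and knockout iTreg libraries. Kcnab3 (adjusted p = 0.0836 and 0.115), Lhx6 (0.598 and 0.786) and Tdg-ps2 (0.0542 and 0.0814) no longer passed without the wild-type or the knockout iTreg library, and Msi1 (0.0605) did not without the knockout resting library. Their log2 folds without these libraries were 1.73 and 1.73 for Kcnab3, 1.68 and 1.68 for Lhx6, 6.26 and 6.19 for Tdg-ps2 and 4.03 for Msi1. Other folds moved by a factor of more than 1.5 while the calls held. Without the wild-type or the knockout resting library the log2 folds were 3.41 and 3.397 for Zan, 9.37 and 9.35 for Hmga1b, 5.93 and 5.92 for Gdpd3, -2.34 and -2.36 for Ccl22, 7.21 and 7.19 for Tdg-ps2 and 5.57 and 5.55 for the gene without a symbol, and 4.05 for Msi1 without the wild-type resting library. Without the wild-type or the knockout stimulated library they were 5.93 and 5.93 for Zan, 6.54 and 6.54 for Hmga1b, 5.66 and 5.66 for Msi1 and 5.04 and 4.81 for Tdg-ps2, and Gm5779 had no wild-type count left in a complete pair to give a fold. Without the wild-type or the knockout iTreg library they were 6.11 and 6.13 for Hmga1b, 8.30 and 8.30 for Gm5779 and 4.09 and 4.09 for the gene without a symbol. Over all alternatives the adjusted p ran up to 0.99998 for Kcnab3 and Lhx6, as for Txnip and Arrdc4, in each case without the cell state as covariate. It ran up to 0.704 for Tdg-ps2 and 0.683 for Msi1, which were not tested in that setting. With median-of-ratios size factors 17 genes passed, and Kcnab3 (0.0563), Lhx6 (0.0606), Ccl22, Trim16 and Tdg-ps2 (0.0652 each) did not, although their log2 folds moved by at most 0.0234 and their standard errors by ratios of 0.984 to 1.02. With the length trend removed 13 of the 22 passed, and Hmga1b (0.0553), Msi1 (0.0784), Lhx6 (0.0798), Kcnab3 and Ccl22 (0.0871 each), AA465934 and Tdg-ps2 (0.116 each) and Spp1 and Trim16 (0.121 each) did not. The log2 folds of these 9 genes moved by at most 0.272, for AA465934 from 2.63 to 2.35 and for Spp1 from 1.27 to 1.07, and their standard errors by ratios of 0.921 to 1.09, so these losses do not show that the effects follow gene length. On log2(FPKM + 1) with limma 10 passed. The others did not, with Hmga1b at 5.98 (adjusted p = 0.157), Ccl22 at -1.20 (0.345), Trim30d at -1.09 (0.372), Trim16 at 1.4996 (0.384), Oasl2 at -1.94 (0.451) and Kcnab3 at 1.26 (0.50036). Lhx6 at 0.80, Msi1 at 1.16, Spp1 at 0.89, Zan at 1.05, Acacb at 0.69 and Tdg-ps2 at 2.70 had an adjusted p of 0.678 each. Adding 1 shrinks the folds of genes with a low FPKM, and on log2(FPKM + 0.1) 7 of the 22 passed. Oasl2 was then among them (-3.39, adjusted p = 0.0253), while Ctse (-2.99, 0.0630), Trim12a (-1.78, 0.0551), AA465934 (2.63, 0.0587) and the gene without a symbol (4.49, 0.133) were lost as well, so both calls and folds depended on the added constant. Without the cell state as covariate edgeR called 0 genes, with 59 at an unadjusted p under 0.05.

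**Figure D2:**
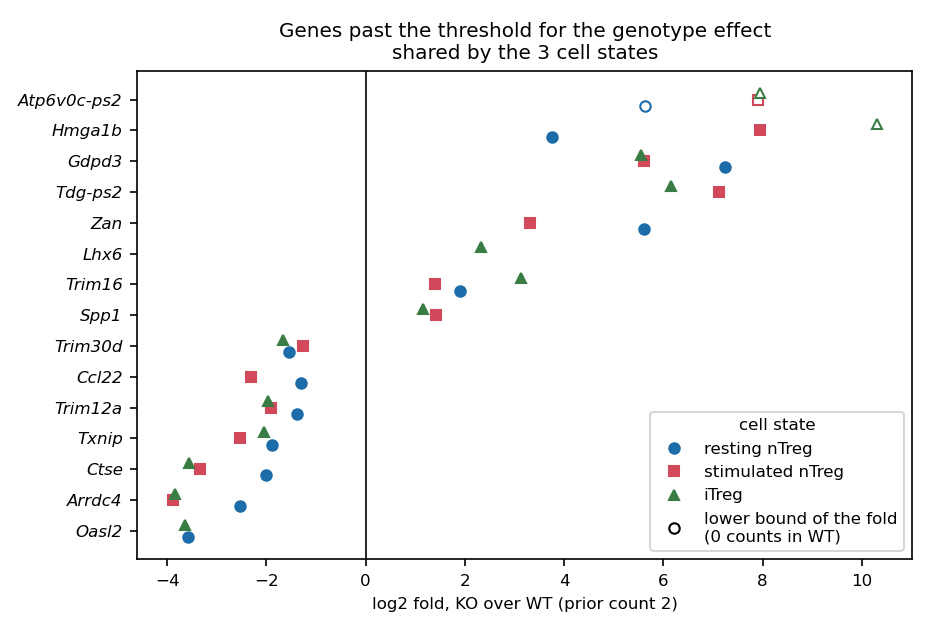
Log2 fold of knockout over wild type in resting (circle), stimulated (square) and iTreg (triangle) cells for the 15 named genes that passed the shared genotype test. Gdpd3 lay at 7.24, 5.60 and 5.55 and Oasl2 at -3.58 in resting and -3.64 in iTreg cells. Open symbols are lower bounds of the fold where wild type had 0 counts, and pairs with under 50 counts in both libraries are not drawn.

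Gene lists fixed before the data were examined were then tested for the shared genotype effect, and 12 of 29 passed. All 12 calls were lost when the correlation between genes was estimated (adjusted p = 0.815 with an estimated correlation for each), so they hold only with the preset correlation. Interferon-stimulated genes fell as a list (median log2 fold -0.63, adjusted p = 2.46e-09). Without the resting pair the median shrank to -0.14 (adjusted p = 0.0285, in a range of 1.48e-21 to 0.815 over the alternatives), so the size of this fall rested on that pair. Of its 20 tested members 1, Oasl2, fell and 19 did not pass, and 8 fell when adjusted over the list alone. Oasl2 lies within 250 gene positions of Mlxip, so the linked segment of another strain weighed further on may account for it. That count covered only the 35 genes changed at least 2-fold the same way in all 3 pairs. The other members of this list were not placed against Mlxip, so the same explanation stays open for them. Rsad2, the antiviral protein viperin, lay at -1.57 (standard error 0.333, adjusted p = 0.205), and Oas2 and Ifit3 at -1.64 and -1.42. The list of naive and resting T cell genes also fell (-0.28, adjusted p = 8.38e-05). None of its 11 members passed over all genes and 3 fell when adjusted over the list alone, with the transcription factor Bach2 at -0.64 and the IL-7 receptor chain Il7r at -0.59, neither past the test over all genes.

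B cell markers rose as a list (median 0.87, adjusted p = 2.46e-09), with 0 of 13 members past the test over all genes and 10 risen when adjusted over the list alone. Without the iTreg pair the median was 0.58 (adjusted p = 2.76e-08, in a range of 3.71e-13 to 0.815). Cd79a, a chain of the B cell receptor, lay at 1.14 (0.321, adjusted p = 0.426) and H2-Eb1, an MHC class II chain, at 1.01 (0.281, adjusted p = 0.417). This difference in B cell markers ran alongside the other list differences of these libraries. The type 1 helper (Th1) list rose as well (0.26, adjusted p = 0.0218), with 0 of 14 members past over all genes and 3 risen when adjusted over the list alone. Ifng, the main Th1 cytokine, lay at 1.88 (0.325, adjusted p = 0.0879) and Cxcr3, a Th1 chemokine receptor, at 1.08 (0.252, adjusted p = 0.263). Without the stimulated pair the Th1 call was lost (adjusted p = 0.0613, in a range of 0.0101 to 0.815 over the alternatives), with a median of 0.24, and without the iTreg pair its median was 0.16.

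Lists of energy metabolism rose by small amounts, with no member past the test over all genes or adjusted over the list alone. The medians were 0.24 for 26 nuclear genes of oxidative phosphorylation (adjusted p = 5.44e-06), 0.21 for 20 glycolytic genes (0.0218), 0.23 for 7 genes of the pentose phosphate pathway (0.0216), 0.16 for 21 genes of the citric acid cycle (0.0218) and 0.22 for 12 genes of fatty acid oxidation (0.0126). Ndufa1, a subunit of complex I, lay at 0.52 (0.196, adjusted p = 0.615) and Tpi1, a glycolytic enzyme, at 0.40. Without the iTreg pair these 5 calls were lost, with adjusted p of 0.105, 0.0941, 0.0866, 0.797 and 0.180 and medians of 0.06, 0.11, 0.11, 0.01 and 0.07 in the same order. Without the resting pair the medians of oxidative phosphorylation and the citric acid cycle were 0.38 and 0.25, and without the stimulated pair that of fatty acid oxidation was 0.35. Without the stimulated pair the calls for glycolysis (0.227), the pentose phosphate pathway (0.0663) and the citric acid cycle (0.0662) were lost, while their medians were 0.23, 0.24 and 0.22, no smaller than with all pairs. Shorter genes were higher in the knockout iTreg library, and removing that trend with gene length ended the calls for oxidative phosphorylation (0.0507), fatty acid oxidation (0.0672), the pentose phosphate pathway (0.0647) and the citric acid cycle (0.191). Over all alternatives the adjusted p ran up to 0.815 for each of these 5 lists, from 4.57e-07 for oxidative phosphorylation, 0.00542 for glycolysis, 0.0209 for the pentose phosphate pathway, 0.00505 for the citric acid cycle and 0.00525 for fatty acid oxidation.

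Targets of the amino acid stress factor ATF4 fell (median -0.21, adjusted p = 0.0218), as did genes induced by the T cell receptor (-0.22, adjusted p = 0.0218), in both lists with no member past the test over all genes or adjusted over the list alone. Asns, asparagine synthetase, lay at -1.22 (0.386, adjusted p = 0.521) and Egr3, an early response factor, at -0.81 (0.346, adjusted p = 0.617). Both calls were lost without the iTreg pair (adjusted p of 0.938 and 0.909, from 0.000173 and 8.69e-05 over the alternatives), with medians of -0.01 and -0.07. The T cell receptor median was -0.38 without the resting and -0.38 without the stimulated pair. The 74 tested ribosomal protein genes rose (0.09, adjusted p = 0.0417), lost that call without the stimulated pair (0.0613) and reversed to a decrease without the iTreg pair (0.0017) and with the length trend removed (5.08e-05), in a range of 1.91e-05 to 0.815, and the median was 0.25 without the resting and -0.11 without the iTreg pair.

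The remaining 17 lists did not pass. Among them the Treg signature had an adjusted p of 0.788, with a median of -0.03 and a mean of 0.04, and the network of MLX-related factors had 0.766, with a median of 0.07 and a mean of -0.07. For hypoxia (0.881) the median was 0.01 and the mean -0.01, and for proliferation (0.683) they were -0.00 and 0.04. The Th17 (0.428), Th2 (0.837), follicular helper (0.528), cholesterol synthesis (0.177), fatty acid synthesis (0.590), homing receptor (0.228), TGF-beta response (0.788) and cytotoxic (0.0667) lists did not pass either. Nor did markers of myeloid (0.788), CD8 or NK (0.139) and erythroid cells (0.771), immediate early and stress genes (0.683) and sex-linked genes (0.139). Over all genes no member of these lists passed, and adjusted over the list alone there were 6 calls: 1 fell in the MLX network, 1 rose for hypoxia, 1 rose and 1 fell among homing receptors, 1 rose in the cytotoxic list and 1 fell among erythroid markers. Without the resting pair 4 of these lists passed, the cytotoxic list (adjusted p = 0.000171, median 0.80 against 0.13 with all pairs), cholesterol synthesis (0.00505, 0.20 against 0.04), CD8 or NK markers (0.0091, 0.54 against 0.32) and sex-linked genes (0.0249, -0.49 against -0.33). Fatty acid synthesis passed with the length trend removed (0.0156, 0.23 against 0.15). Over the settings tried, the adjusted p of these 5 lists ran up to 0.99542, 0.815, 0.938, 0.938 and 0.815 in the order given. The single tested stromal marker did not pass.

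In resting nTreg cells, the direct comparison of the 2 libraries put interferon-stimulated genes lower in the knockout. All 20 were below 0, 15 of them at least 2-fold, with a median log2 fold of -1.34, below all 10000 random lists of matched expression (percentile 0). Oas2 went from 53.8 to 6.66 CPM (-2.98, -3.40 to -2.65), Ifit3 from 238 to 33.7 (-2.81, -2.99 to -2.66) and Oasl2 from 75.9 to 6.18 (-3.58, -4.01 to -3.25). Follicular helper genes were higher (median 0.53, percentile 100, 6 of 9 above 0), with Tox2, a transcription factor, at 1.25 (1.01 to 1.52) and Pdcd1, the inhibitory receptor PD-1, at 1.11 (1.01 to 1.21). Homing receptors were higher too (0.29, percentile 99.99, 14 of 20 above 0), with Cxcr3 at 1.52 (1.39 to 1.65), while naive genes were lower (-0.37, percentile 0.01, 7 of 11 below 0), with Bach2 at -0.73. The Treg signature had a median of 0.02 (percentile 71.1) and a mean of -0.01, with 14 of 28 members above 0. Of these members 2 were at least 2-fold higher, the inhibitory receptors Tigit at 1.49 (1.39 to 1.59) and Klrg1 at 1.13 (0.89 to 1.39), and 2 lower, the receptor Gpr83 at -1.28 (-1.42 to -1.15) and the granzyme Gzmb at -1.18 (-1.45 to -0.93).

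Across all genes considered in resting cells, 146 were at least 2-fold higher and 150 lower in the knockout, of 10324. The largest increases were Gdpd3 (0.896 to 165 CPM, log2 fold 7.24), Eno1b (0 to 19.2 CPM, at least 64.4-fold), Atp6v0c-ps2 (at least 49.7-fold), Zan (5.62, 4.92 to 7.30), Msi1 (4.37, 3.38 to 11.24, from 1 count in wild type), Hmga1b (3.75), Sh3rf2 (3.39) and AA465934 (3.14). Eno1b, like Hmga1b and Atp6v0c-ps2, has a near-identical parent, so its reads are uncertain. Beside Oasl2, Oas2 and Ifit3, the largest decreases were the hemoglobin genes Hbb-bt (-3.61), Hba-a2 (-2.97) and Hba-a1 (-2.90), which are markers of red blood cells, the interferon-inducible Ifit3b (-2.91) and the peptide transporter Slc15a2 (-2.68). B cell markers moved with these groups, with a median of 0.68 (percentile 100, 11 of 11 members above 0), and Cd79a stood at 21.9 CPM in wild type and 41.1 in the knockout (0.90, 0.67 to 1.15). Ribosomal protein genes had a median of -0.23 (percentile 0, 64 of 74 below 0), cholesterol synthesis -0.18 (0.74, 15 of 19), ATF4 targets -0.18 (1.40, 11 of 17) and the cytotoxic list -0.50 (1.69, 4 of 4).

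In stimulated nTreg cells the knockout library had higher levels of lipid synthesis, Th1 and cytotoxic genes. All 19 cholesterol synthesis genes were above 0 (median 0.44, percentile 100), with the farnesyl diphosphate synthase Fdps at 0.63. Of 8 fatty acid synthesis genes 7 were above 0 (0.33, percentile 100), with the stearoyl-CoA desaturases Scd1 at 2.18 (1.73 to 2.78) and Scd2 at 1.70 (1.62 to 1.78). The Th1 list had a median of 0.36 (percentile 100, 10 of 13 above 0), with Ifng at 1.92 (1.63 to 2.26), Nkg7 at 1.30 (1.12 to 1.49) and Tbx21, which encodes T-bet, at 1.01 (0.88 to 1.14), and the cytotoxic list had 0.81 (percentile 100, 4 of 4). Glycolytic genes were higher in 18 of 20 cases (0.20, percentile 100), with Hk2, the inducible hexokinase, at 0.57 (0.43 to 0.71), and proliferation genes in 22 of 25 (0.14, percentile 99.6). Naive genes were lower (-0.14, percentile 0.08, 8 of 11 below 0). B cell markers had a median of 0.33 (percentile 99.9, 10 of 11 above 0) and sex-linked genes one of -0.30 (percentile 0.16, 3 of 4 below 0) here, and Treg signature genes one of -0.01 (percentile 1.89, 16 of 28 below 0) with a mean just above 0.

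Fewer genes lay beyond 2-fold in this state, with 55 higher and 52 lower of 10142. The 124 of 9932 unchanged genes beyond 2-fold in a simulated pair cannot serve as a yardstick for this number. They came from a simulated iTreg pair, with a spread in which effects specific to a state count as error. The log2 folds of the real pairs had interquartile ranges of 0.25 in stimulated and 0.73 in iTreg cells. The largest increases were Atp6v0c-ps2 (at least 241-fold), Hmga1b (7.95), Tdg-ps2 (7.11), Gdpd3 (5.60, 4.81 to 8.06), Tmem254b (3.59), Zan (3.31), Ntn4, a netrin (2.69, 2.09 to 3.66) and Acacb (2.59, 1.85 to 3.93). The largest decreases were Tmem254c (-7.28, -11.31 to -6.41, 2 counts in the knockout), Ifi204 (5.63 CPM to 0, at least 18.4-fold lower), Arrdc4, Ctse (-3.33, -3.66 to -3.06), Apobec2 (-3.23), Eaf2 (-2.68), Txnip and Rtl1 (-2.43). Tmem254b and Tmem254c are copies of each other, so their opposite values may come from shared reads.

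In iTreg cells 271 genes were at least 2-fold higher and 536 lower of 10214, the largest numbers of the 3 states. These folds followed gene length, as the Spearman correlation across genes between length and log2 fold was -0.56 in this pair, against -0.18 and -0.13 in the resting and stimulated pairs. The median log2 fold went from 0.45 in the shortest of 5 equal groups of genes by length (median 1188 bases) to -0.45 in the longest (6095 bases). With the trend removed, 218 genes were higher and 384 lower.

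**Figure D3:**
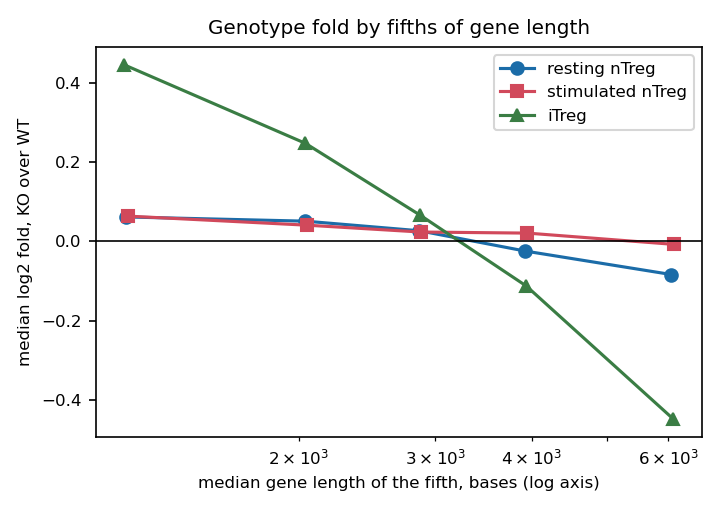
Median log2 fold of knockout over wild type in 5 equal groups of genes by transcript length (bases, log axis), for the resting, stimulated and iTreg pairs. In iTreg cells the medians went from 0.45 through 0.25, 0.07 and -0.11 to -0.45.

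Genes induced by the T cell receptor were lower in knockout iTreg cells (median -0.76, percentile 0, 11 of 14 below 0), and at -0.94 with the length trend removed. Egr3 was at -1.96 (-2.13 to -1.80) and the orphan nuclear receptors Nr4a3 and Nr4a2 were at -1.78 and -1.70. ATF4 targets were lower too (-0.41, percentile 0.22, 17 of 19 below 0, and -0.71 with the trend removed), with Asns at -2.47 (-2.72 to -2.26) and the glutathione-degrading enzyme Chac1 at -2.18. Cytotoxic genes were higher (0.86, percentile 99.9, 5 of 6 above 0, and 0.48 with the trend removed), with granzymes Gzma at 3.50 (2.83 to 4.75) and Gzmc at 2.84 (2.33 to 3.58), and Ifng was at 2.69 (2.40 to 3.05). CD8 and NK markers, which were higher beside them, had a median of 0.84 (percentile 99.8, 4 of 4 above 0, and 0.46 with the trend removed). All 26 oxidative phosphorylation genes were above 0 (0.58, percentile 100), but the median was 0.17 with the trend removed. For the citric acid cycle, fatty acid oxidation and glycolysis the medians were 0.48, 0.40 and 0.35, with 19 of 21, 12 of 12 and 15 of 20 members above 0, against 0.17, 0.17 and 0.25 with the trend removed. B cell markers had a median of 1.92 (percentile 100, 10 of 10 above 0, and 1.55 with the trend removed), with Cd79a at 3.57 CPM in wild type and 18.1 in the knockout. Beside them the sex-linked list had a median of -0.88 (percentile 0.25, 4 of 4 below 0, and -0.77 with the trend removed), with the Y-linked Ddx3y at 115 and 45.7 CPM. Naive genes were lower (-0.44, percentile 0.50, 9 of 11 below 0), and the Treg signature and interferon-stimulated genes had medians of -0.02 (percentile 22.2, 13 of 25 below 0, with a mean of 0.07) and -0.01 (percentile 39.0, 7 of 14 below 0, with a mean of -0.20). With the trend removed these medians were 0.02 (percentile 34.8) and -0.24 (percentile 5.78), and that of naive genes was -0.30. Ribosomal protein genes had a median of 0.48 (percentile 100, 73 of 73 above 0) that reversed to -0.07 with the trend removed.

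The largest single increases in iTreg cells were Hmga1b (0 to 386 CPM, at least 1263-fold), Atp6v0c-ps2 (at least 249-fold), the metallothioneins Mt2 (0 to 48.4 CPM, at least 158-fold) and Mt1 (6.96), which bind zinc and other metals, Tdg-ps2 (6.15), Gdpd3 (5.55), Ntn4 (5.22) and the neuropeptide Gal (0 to 5.22 CPM, at least 17.1-fold). Among the largest decreases were Ifi204 (-5.32, -12.18 to -4.36, 1 count in the knockout), Arrdc4, Oasl2 (-3.64), Ctse (-3.56, -4.04 to -3.21), the arginine transporter Slc7a3 (-3.20, -4.53 to -2.49), the isoprenoid enzyme Idi2 (-3.19) and the activity-regulated factor Npas4 (-3.13, -3.74 to -2.69).

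**Figure D4:**
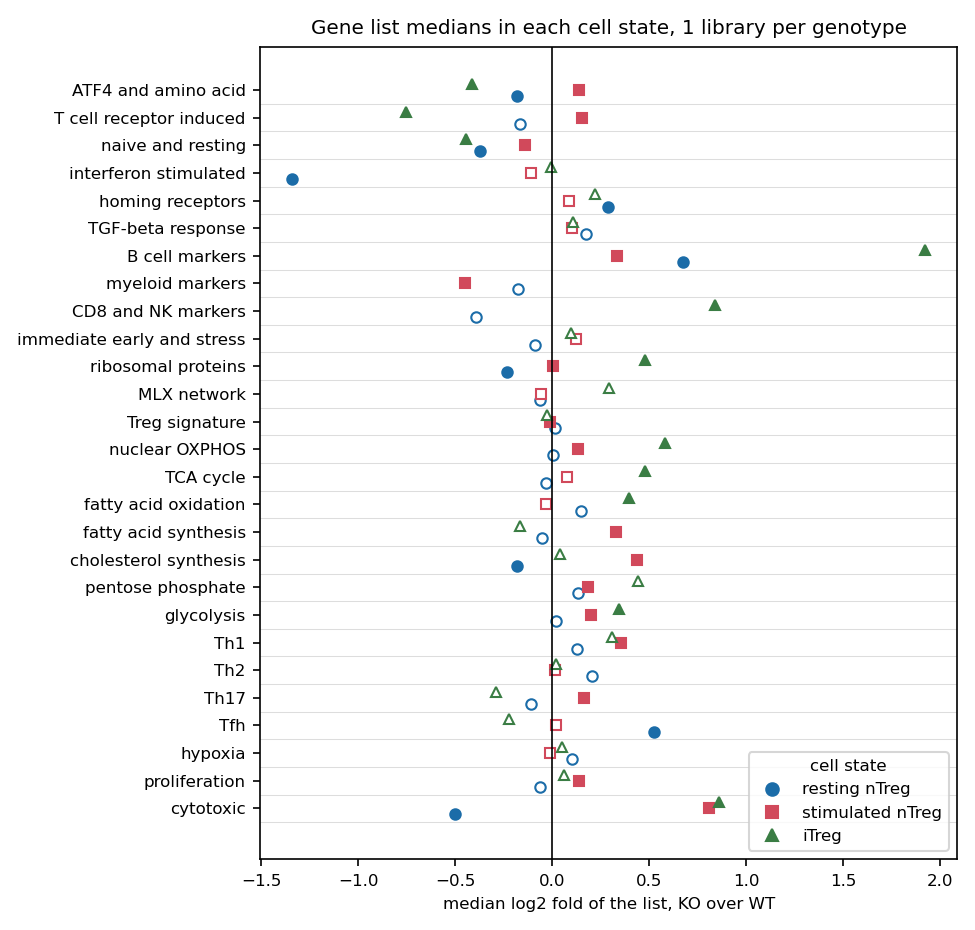
Median log2 fold of knockout over wild type for 27 gene lists in resting (circle), stimulated (square) and iTreg (triangle) cells, with filled symbols where the median lay outside the middle 95% of 10000 random matched lists. Interferon-stimulated genes lay at -1.34 in resting cells and -0.01 in iTreg cells, and B cell markers at 0.68, 0.33 and 1.92.

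Genotype differences were compared between states across 9394 genes, which are not independent replicates. Pearson correlations of the log2 folds were 0.27 between resting and stimulated, 0.36 between resting and iTreg and 0.42 between stimulated and iTreg cells, and Spearman correlations were 0.00, 0.27 and 0.25. Of 11072 genes with at least 50 counts in the higher library of at least 1 pair, 19 were at least 2-fold higher and 16 at least 2-fold lower in all 3 pairs. Independent pairs would give 0.0513 and 0.117. The count minimum was not applied within each pair, so the 19 include Lhx6 and Zan, which had too few counts in some pairs to give a direction.

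The response of nTreg cells to stimulation was broadly shared by the genotypes. Across 10820 genes the 2 responses had a Pearson correlation of 0.92, with 1425 genes at least 2-fold up in both, 1135 down in both and 8 in opposite directions. The responses differed at least 2-fold for 263 genes that were higher and 290 that were lower in the knockout, a difference that could not be tested with 1 library per group. Resting and stimulated libraries also differed in sex by their sex-linked genes, as described with stimulation, so sex and stimulation cannot be told apart here. Scd2 had a log2 fold response of 3.70 in knockout and 1.61 in wild-type cells, and Prf1, the pore-forming protein perforin, had 1.53 against -0.29. Il12rb2, a chain of the IL-12 receptor, had responses of 4.42 and 1.89, and Ifit3 had -4.38 against -6.51. Tigit had -0.71 in knockout and 0.82 in wild-type cells. The resting libraries already differed, with log2 folds of knockout over wild type of -0.39 for Scd2, -0.89 for Prf1, -2.16 for Il12rb2 (54 and 11 counts in wild type and knockout), -2.81 for Ifit3 and 1.49 for Tigit.

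Stimulated nTreg cells were then compared with resting cells, with the genotypes as the samples of each state. Of 12848 genes 3100 rose and 2867 fell, and without the knockout stimulated library 2118 rose and 1676 fell. All 25 proliferation genes rose (adjusted p of the list 2.88e-20, and 0.506 with an estimated correlation), among them the mitotic kinases Bub1 at 5.29 (standard error 0.254, adjusted p = 2e-06) and Aurkb at 5.11. Of 20 glycolytic genes 14 rose and 1 fell (adjusted p = 0.000126, and 0.668 with an estimated correlation), led by Hk2 at 3.56 (0.328, adjusted p = 4.4e-05). Of 19 cholesterol synthesis genes 16 rose, or 17 adjusted over the list alone (3.53e-06, and 0.668 with an estimated correlation), with the sterol demethylase Cyp51 at 2.63 (0.237, adjusted p = 4e-05). Of 19 ATF4 targets 13 rose and 1 fell (0.000224, and 0.671 with an estimated correlation), with Asns at 3.62 (0.5, adjusted p = 0.000439). Of 14 genes induced by the T cell receptor 11 rose and 2 fell (0.000675, and 0.668 with an estimated correlation), with Egr3 at 5.12 (0.474, adjusted p = 4.5e-05). Of 28 Treg signature genes 14 rose and 2 fell, or 3 adjusted over the list alone (0.00757, and 0.577 with an estimated correlation), with Gzmb at 4.54 (0.487, adjusted p = 0.000104) and the cytokine Il10 at 3.05 (0.279, adjusted p = 4.3e-05). Foxp3 lay at -0.52 and did not pass (0.192, adjusted p = 0.0503).

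Several lists fell on stimulation. Of 11 naive genes 10 fell (adjusted p = 1.3e-05, and 0.506 with an estimated correlation), with the transcription factor Tcf7 at -3.05 (0.214, adjusted p = 9e-06). Of 20 interferon-stimulated genes 16 fell and 1 rose (1.99e-07, and 0.668 with an estimated correlation), with Ifit1 at -4.96 (0.309, adjusted p = 5e-06). Markers of myeloid cells fell in 10 of 11 cases (0.000138, and 0.506 with an estimated correlation) and B cell markers in 7 of 13 (0.00754, and 0.720 with an estimated correlation). Both lists mark other cell types that a sort could hold. A loss of such cells and a change within Treg cells cannot be told apart here. Oxidative phosphorylation (6 of 26 rose, 0.00711, and 0.755 with an estimated correlation) and the citric acid cycle (9 of 21 rose, 0.0259, and 0.755 with an estimated correlation) also passed. Txnip fell by -3.73 (0.241, adjusted p = 6e-06) and Arrdc4 by -1.12 (0.401, adjusted p = 0.0449), while Slc2a1 rose by 1.16 (0.18, adjusted p = 0.000806) and Mlxip did not pass (-0.13, adjusted p = 0.653).

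The largest increases among expressed genes were the histone genes H2ac23 (0 counts in the resting libraries, at least 176-fold), H2ac11 (at least 73.5-fold) and H2ac24 (6.82), the steroid dehydrogenase Akr1c18 (8.19, 0.473, adjusted p = 3e-06), Spp1 (7.76, 0.302, adjusted p = 2e-06), Tdg-ps2 (6.97, a copy), the DNA recombination factor Hrob (6.86) and the transporter Slc4a11 (6.80). The largest decreases were Apol7c (-8.16, 0.534, adjusted p = 7e-06), the neutrophil genes Ngp (-7.32) and S100a8 (-6.86), Rsad2 (-6.67), Ramp3 (-6.66), Tsix (-6.43), the actin-bundling Fscn1 (-6.29) and Jchain (-5.90), which joins antibody units in plasma cells. Tsix, the X-linked antisense partner of Xist, was not on the sex-linked list but follows sex, with 300 and 179 counts in the resting and at most 4 in the other libraries. Both resting libraries had 0 counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty and Xist at 710 and 499 CPM, whereas the other 4 libraries held Ddx3y at 45.7 to 115 CPM. Stimulated cells had at least 265-fold and iTreg cells at least 275-fold more Ddx3y, so by these genes the comparisons with resting cells also compare mice of different sex, and the sex-linked list passed in both (adjusted p = 0.00711 and 0.00576, and 0.668 and 0.527 with an estimated correlation). With genes at 0 set to their bound, the medians of that list were 7.24 and 7.02, and 4 members rose and 1 fell in each comparison.

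Other lists did not pass the set test on stimulation although members did. The Th1 list had 6 risen and 5 fallen of 14, or 7 and 5 adjusted over the list alone, with Tbx21 at 3.82 (0.261, adjusted p = 8e-06) and the chemokine Ccl5 at -4.03. The Th17 list had 3 and 5 of 13, the follicular helper list 2 and 6 of 10 with Bcl6 at -2.79, homing receptors 5 and 12 of 21, fatty acid synthesis 4 and 1 of 8 and hypoxia 6 and 2 of 12. The pentose phosphate pathway had 4 and 0 of 7, fatty acid oxidation 1 and 3 of 12 (median 0.00, mean -0.06), the cytotoxic list 3 and 1 of 7, immediate early genes 3 and 4 of 13, the MLX network 2 and 1 of 10 and ribosomal proteins 6 and 5 of 74, or 3 and 2 adjusted over the list alone. The Th2 list had 2 and 0 of 7, with a median of -0.37, a mean of 0.54 and an upward test direction. TGF-beta response genes had 2 and 2 of 7, or 3 and 2 adjusted over the list alone, CD8 or NK markers 1 and 1 of 4, and erythroid markers 0 and 2 of 3.

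The last comparison set iTreg cells against resting nTreg cells. Of 12848 genes 3068 rose and 3062 fell, and without the knockout resting library 2066 rose and 1987 fell. All 25 proliferation genes rose (adjusted p = 5.46e-20, and 0.512 with an estimated correlation), with the topoisomerase Top2a at 5.49 (standard error 0.272, adjusted p = 2e-06). Of 19 ATF4 targets 17 rose (1.13e-06, and 0.527 with an estimated correlation), with the stress protein Nupr1 at 8.46 (0.61, adjusted p = 1e-05). Cholesterol synthesis had 16 risen of 19 (3.64e-06), fatty acid synthesis 6 risen and 1 fallen of 8 (0.0117), glycolysis 13 and 3 of 20 (0.00726) and T cell receptor-induced genes 11 and 3 of 14 (0.00521), each with an adjusted p of 0.527 with an estimated correlation. Scd2 rose by 4.33 (0.509) and Cyp51 by 2.33. Oxidative phosphorylation had 7 risen of 26 (0.00521, and 0.693 with an estimated correlation) and ribosomal proteins 17 risen and 2 fallen of 74, or 12 and 2 adjusted over the list alone (0.0117, and 0.750 with an estimated correlation).

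Parts of the Treg programme were lower in iTreg than in resting cells. Of 28 signature genes 15 fell and 7 rose, or 16 and 8 adjusted over the list alone (adjusted p = 0.0277, and 0.521 with an estimated correlation), and the falls included Ikzf2, which encodes the thymic Treg factor Helios, at -4.58 (0.358, adjusted p = 1.4e-05), Ebi3, a subunit of IL-35, at -3.89 and Il10 at -3.66. Foxp3 fell by -0.60 (0.192, adjusted p = 0.0283) and Txnip by -2.40 (0.227, adjusted p = 4.4e-05), Slc2a1 rose by 0.70 (0.179, adjusted p = 0.0107), and Arrdc4 (0.82, adjusted p = 0.0937) and Mlxip (-0.19, adjusted p = 0.513) did not pass. Homing receptors fell in 14 and rose in 3 of 21 cases (0.000272, and 0.512 with an estimated correlation), with Ccr2 at -5.68. Follicular helper genes fell in 7 of 10 (0.00286, and 0.512 with an estimated correlation) and naive genes fell in 7 and rose in 1 of 11, or 8 and 1 adjusted over the list alone (0.00343, and 0.512 with an estimated correlation). Interferon-stimulated genes fell in 14 and rose in 2 of 20 cases, or 16 and 2 adjusted over the list alone (3.45e-05, and 0.527 with an estimated correlation). Myeloid markers fell in 11 of 11 cases (6.52e-06, and 0.512 with an estimated correlation), with a median of -3.53 when genes at 0 were set to their bound, and B cell markers in 9 of 13, or 11 adjusted over the list alone (0.000312, and 0.527 with an estimated correlation). Here too, other cells in the resting sort and a difference between Treg cells cannot be told apart. CD8 and NK markers rose in 4 of 4 (0.00726, and 0.521 with an estimated correlation), with Cd8a at 3.80 (0.409, adjusted p = 9.5e-05).

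The largest increases in iTreg cells were the acyl-CoA synthetase Acsl6 (0 counts in the resting libraries, at least 222-fold), the imprinted transcript H19 (at least 219-fold), H2ac23 (at least 162-fold), Akr1c18 (10.82, 0.426, adjusted p = 2e-06), H2ac11 (at least 24.9-fold), Plekhd1 (8.77), the gap junction gene Gja1 (7.58) and the chemokine Xcl1 (7.54). Genes at 0 in both iTreg libraries included Ngp (at least 336-fold lower), S100a8 (at least 117-fold), Klrg1 (at least 103-fold), Ces2c (at least 88.6-fold), Tsix (at least 76.5-fold) and Naip6 (at least 46.8-fold), and Apol7c and S100a9 fell by -9.52 and -9.09. Among lists that did not pass, the Th17 list had 4 risen and 7 fallen of 13, with Ccl20 at 6.89 and Rora at -5.15, and the Th1 list 6 and 6 of 14, or 7 and 6 adjusted over the list alone. The Th1 median was 0.31 and its mean 0.07, with a downward test direction. The Th2 list had 1 and 2 of 7, the pentose phosphate pathway 5 and 1 of 7, the citric acid cycle 2 and 0 of 21, hypoxia 6 and 2 of 12 with Vegfa at 4.89, and fatty acid oxidation 2 and 2 of 12. TGF-beta response genes had 3 and 1 of 7, or 4 and 2 adjusted over the list alone, the cytotoxic list 4 and 0 of 7, or 5 adjusted over the list alone, and the MLX network 3 and 2 of 10, or 4 and 2 adjusted over the list alone. Immediate early genes had 3 and 5 of 13 and erythroid markers 0 and 2 of 3.

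**Figure D5:**
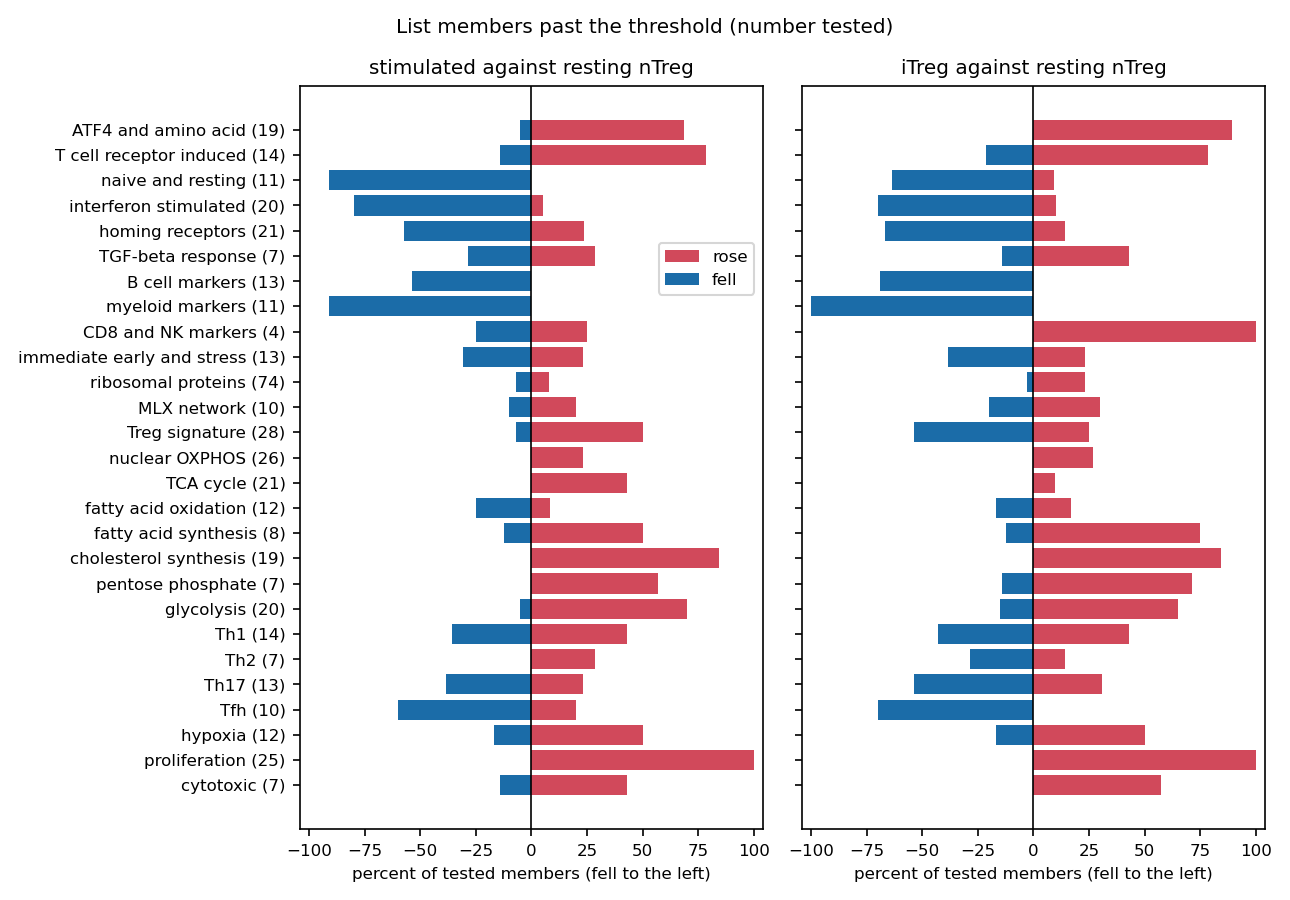
Percent of tested list members that rose (right) or fell (left) in stimulated nTreg cells and in iTreg cells, each against resting nTreg cells. All 25 proliferation genes rose in both comparisons, and 16 and 14 of 20 interferon-stimulated genes fell.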

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

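The neighbourhood, depth, other-pair and gap tests and the count of splits were chosen after the result was seen, and the copy, isoform, GC content and second B cell list tests before.

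Of the list medians, 7 differences stood out because both medians lay outside the middle 95% of random lists and in opposite directions in 2 cell states, and none of these differences was tested. Cholesterol synthesis genes had a median log2 fold of knockout over wild type that was 0.62 higher in stimulated than in resting nTreg cells. For ATF4 targets the median in stimulated cells was 0.32 above that of resting and 0.55 above that of iTreg cells. For genes induced by the T cell receptor it was 0.91 higher in stimulated than in iTreg cells. The cytotoxic list was 1.31 higher in stimulated and 1.36 higher in iTreg than in resting cells. Ribosomal protein genes were 0.71 higher in iTreg than in resting cells, and this difference goes with the length trend of the iTreg pair. By their sex-linked genes the resting libraries also differed in sex from the rest. Sex and cell state therefore cannot be told apart in the differences from resting cells.

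The first pattern weighed was the group of 35 genes changed at least 2-fold in the same direction in all 3 genotype pairs, with the count minimum met in at least 1 pair. The group includes Lhx6 and Zan, which had too few counts in some pairs to give a direction, and Zan is also among the 5 genes counted near Mlxip. For Hmga1b and Atp6v0c-ps2, shared reads are a candidate explanation, since the sum of copy and parent differed between genotypes by a median absolute log2 ratio of 0.252, but for Atp6v0c-ps2 in resting cells the parent was no lower in the knockout (108 and 109 CPM while the copy stood at 0 and 14.8), so there the question stays open. A linked segment of another strain around the targeted gene may account for part of the group, since 5 of these genes (Zan, Msi1, Acacb, Oasl2 and Ccdc62) lay within 250 gene positions of Mlxip, where 10000 random draws gave a median of 1 and at most 6. It cannot account for the 28 genes on other chromosomes, of the 34 with a known place, which include Txnip, Arrdc4 and Gdpd3. Of these 28, 11 lay within 25 positions of another such gene, where random draws gave a median of 2 and at most 12, so segments elsewhere in the genome stay open, as does an effect of losing MondoA.

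The second pattern was the lower level of longer genes in the knockout iTreg library. A ratio of total counts of 1.04 argues against sequencing depth. The tables also argue against GC content in place of length, since the rank correlation of length and fold stayed at -0.55 given GC content against -0.56 without it, but that of GC content and fold was 0.405, or 0.376 given length, so a trend with GC content beside length stays open. They argue against an effect of genotype common to the 3 states, since the strongest correlation in the other pairs was -0.18. RNA or library quality that depends on length remains a candidate explanation. Of the genes with several transcripts whose length differed, 63.0% had a shorter weighted length in the knockout iTreg library, against 51.5% and 52.7% in the resting and stimulated pairs. The shift in length was small, with a median log2 length ratio of -0.0036 against -0.0012 and -0.0013. An effect of genotype specific to iTreg cells stays open as untested.

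For the third pattern, higher B cell markers in the knockout libraries, a lower share of T cells, which would raise every other cell type alike, is argued against in resting cells, where the myeloid and the CD8 or NK medians both lay at least 0.85 below that of the B cell list. More B cells among the cells sequenced may be a source, although the CD4+CD25hiYFP+ gate should remove them from the sorted nTreg cells and naive CD4 cells were sorted for the iTreg culture. A second list of B cell genes had medians of 0.59, 0.19 and 0.48 in resting, stimulated and iTreg cells, with 0.19 the lowest, against 0.68, 0.33 and 1.92 for the first list. Of the abundant B cell genes, Cd74 stood at 220 and 319 CPM and Cd79a at 21.9 and 41.1 CPM in wild-type and knockout resting cells, and all 13 first-list members had counts enough to be tested in these T cell libraries. B cells and expression of these genes by the T cells cannot be told apart here, because the second list was above 0 in all states, yet with 6 of 10 members above 0 in iTreg cells it fell far short of the first.

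The count of 22 genes with a shared genotype effect was compared with the other ways of dividing the 6 libraries into 3 and 3. The 10 possible splits are too few for a share under 0.05, and 3 of them, the real one included, gave at least as many genes, with 786 the highest of the others. The 3 other splits that, like the real one, put 1 library of each state on each side called 0, 0 and 1 genes, and these splits are too few as well. The count of 786 came from the 2 splits that set the resting libraries and 1 iTreg library against the rest. With the cell state in the model both rest on the knockout and wild-type iTreg libraries alone, so they are 1 comparison counted 2 times. That comparison is itself one of genotype, so these splits cannot serve as a reference for the real one. A genotype effect in iTreg cells and a difference between these 2 samples cannot be told apart here.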

How the results depend on the processing

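Tests with the length trend removed, with log2(FPKM + 0.1) and with other settings for the response were chosen after the data were seen, and all others before.

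For every result in this paragraph the cause was not tested unless stated. With a count minimum of 20, 225 genes were higher and 249 lower in resting, 105 and 118 in stimulated, and 409 higher in iTreg cells. With 200 these were 57 and 87, 31 and 17, and 151 and 355, since fewer genes were considered. With FPKM values 124 genes were higher and 109 lower in stimulated cells. The 22 shared genotype genes became 67 without a filter, 67 with DESeq2, 10 with limma on log2(FPKM + 1), 7 on log2(FPKM + 0.1), 0 without the state as covariate by edgeR (59 at an unadjusted p under 0.05) and 14 with the length trend removed, and 34 to 305 when 1 library was left out (35 and 34 without the wild-type and knockout iTreg, 235 and 233 resting, and 302 and 305 stimulated library). Of the 22, 21 also passed with DESeq2, 22 without a filter, 13 with the length trend removed and 19 to 22 with 1 library left out. With 1 library left out stimulation gave 3794 (knockout stimulated library left out) to 7575 and iTreg polarization 4053 (knockout resting library left out) to 6541 genes, and the group left with 1 library was assumed to vary like the others. In place of 12 lists with a shared genotype effect, 0 passed with an estimated correlation, and 5 to 16 with a pair left out (7 without the stimulated and 5 without the iTreg pair). With a count minimum of 200 the responses differed for 135 genes higher and 122 lower in the knockout.

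The ribosomal protein list reversed from a rise to a fall without the iTreg pair (adjusted p = 0.0017, in a range of 1.91e-05 to 0.0613 with a pair left out) and with the length trend removed (5.08e-05). Its median turned to -0.0046 in stimulated cells with median-of-ratios factors, and to -0.0701 in stimulated and -0.0736 in iTreg cells with the length trend removed; the cause was not tested. Among the main values of the comparisons 60 of 92 alternatives stayed within the range set for no change, and 32 moved. Among single genes and lists 364 kept their side of the threshold, 97 lost it, 11 moved and 5 reversed. Depth limits ratios of genes with few counts, such as Msi1 in resting cells, whose interval ran from 3.38 to 11.24.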

Other observations

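The genes in this part were picked singly, only after their values were seen, belong to no list fixed beforehand, and were not tested, so they show nothing about the groups they come from.

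In knockout iTreg cells Mt1, a metallothionein, had a log2 fold of 6.96 over wild type, against 1.08 in resting and 0.71 in stimulated cells. Its resting value rests on 8 counts in wild type and 20 in knockout (0.01 to 2.65). Mt2, a relative of Mt1, stood at 0 and 48.4 CPM in wild-type and knockout iTreg cells, at 3.82 and 4.91 CPM in stimulated cells, and at 3 and 1 counts in resting cells. The zinc exporter Slc30a1 was at 2.01 (1.41 to 2.87) in iTreg cells, against -0.03 and 0.38 in resting and stimulated cells. The zinc importer Slc39a10 was at -1.74 (-1.99 to -1.52), or -1.46 with the length trend removed, against -0.09 and -0.74. The cystathionine lyase Cth was at -2.55 (-3.74 to -1.85) in iTreg cells and the alanine transaminase Gpt2 at -2.36 (-2.96 to -1.91). The transcription factor Atf5 was at -1.61 in iTreg cells, against 0.47 and 0.66 in resting and stimulated cells.

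For 6 interferon-inducible GTPase genes, log2 folds in resting cells were -2.48 for Gbp10, -1.77 for Tgtp1, -1.43 for Iigp1, -1.37 for Gbp6, -1.29 for Gbp4 and -1.21 for Igtp. In stimulated cells they lay at -0.30, 0.20, 0.30, -0.20, -0.31 and 0.05 in the same order, and in iTreg cells at -1.17, 0.44, 0.46, -0.33, -0.88 and 0.35. The chemokine Ccl3 was at -0.78 in resting, 1.23 in stimulated and 1.40 in iTreg cells, Ccl4 at -0.98, 1.74 and 0.63, Xcl1 at 1.53, 1.17 and 0.94, and the cytokine lymphotoxin Lta at -1.30, 0.80 and 0.91. With the length trend removed the iTreg values of these 4 were 0.88, 0.07, 0.30 and 0.54. The resting values of Ccl4 and Xcl1 rest on few counts, 17 and 8 (-2.57 to 0.14) and 3 and 13 (0.19 to 4.50) in wild type and knockout. None of these differences between states was tested.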
